A study of Caenorhabditis elegans with 6 samples.

How the data were processed

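Total RNA of 6 samples, 3 of an ung-1 mutant and 3 of wild type N2, was extracted with Trizol, labelled with biotin and hybridised to Affymetrix C. elegans genome arrays, per the labels' protocols. Samples were grouped by their titles, which call the replicates biological; nothing further says how the cultures were separated. The deposited table holds 1 intensity per probe set and array on a linear scale, for 22625 probe sets. The software and the method that summarised the probes, any background correction and any scaling between arrays are not given in the sources used here. The medians of the 6 arrays, from 152.82 to 167.85, were close to each other, but whether the authors scaled them is unknown. No detection calls were used, and the distance of a dim probe set from background is unknown.

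The deposited intensity values held 1364 whole numbers from 10959 upwards among values otherwise written with up to 2 decimals, and the highest of the remaining values was 22439.8. Of these numbers, 1361 equal day counts that a spreadsheet uses for dates, either days of 1 calendar year or the first of a month in years from 1930 to 2029. They were taken as small values read as dates, and each was turned back into the number that a spreadsheet would have read as that date, day.month in 631 cells and month.year in 730 cells. The restored values lie between 1.17 and 31.12, in 605 of the probe sets tested. The plan made before the data were examined was to use the values as the table gives them. The restored values were used in its place, a choice made from the number patterns alone, before any comparison of the groups was fitted. The values as deposited, the setting first planned, were run as an alternative, and so were date cells set to missing, an alternative chosen after seeing the data.

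Probe sets were named from the array's platform annotation, with symbols checked through gene identifiers against RefSeq genes of assembly WBcel235, which changed 0 symbols. Of the 22548 probe sets tested, 20766 carried 1 gene symbol, 887 several and 895 none; only the first kind was named. Of these, 20701 had an entry in the gene table. The 77 Affymetrix control probe sets were left out of all tests. Probe sets with identifiers ending in _s_at, _x_at or _a_at can match several transcripts.

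Intensities were tested as log2(intensity + 16) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all 22548 probe sets and a threshold of 0.05. The offset of 16 understates the fold change of dim probe sets. No further normalization between arrays and no filter on dim probe sets were applied. Gene lists were tested with camera at a preset correlation of 0.01 on 1 probe set per gene, that with the highest mean, adjusted over the 27 lists with at least 5 measured members. The lists covered DNA repair (3 lists), cell death and engulfment, DNA replication, germline and oocyte, sperm, major sperm proteins, yolk, embryonic regulators, cuticle collagens, moulting, dauer and starvation, male-enriched neurons, muscle, neurons, intestine, heat shock, detoxification, innate immunity, fatty acid metabolism, ribosome, proteasome, mitochondria, histones and small RNA pathways. The exact permutation tests of single values used all 20 regroupings of 3 against 3 arrays. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

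Named genes followed a rule written beforehand. It took ung-1, 6 cell death genes (egl-1, ced-13, ced-3, ced-4, ced-9 and cep-1), and up to 12 genes per direction among those past the threshold. These had to name 1 gene, have a mean above the 25th percentile and have the groups apart. Where fewer than 5 passed in a direction, the list was filled up to 5 by the smallest unadjusted p among genes meeting the same conditions, and these are given as values that did not pass. In each gene list up to 4 members past the threshold were named, or else the member with the smallest p, and lists without a call could be summarised with no member named. A member chosen by smallest p is given by that probe set alone unless the text says otherwise, and other probe sets of the gene can differ. The further members named as examples (col-98, pas-4, rpn-10, daf-22, elo-5, cyp-13B1, hsp-1, hsp-16.41, cpg-1, parp-2 and T05E12.6), the neighbours of ung-1, and genes named first in the closing section were chosen after their values were seen.

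The tests were run on simulated arrays built on the 22548 real probe sets, with 100 changed 2-fold and 100 changed 4-fold. Limma called 33 and 93 of them, with 8 false calls, and kept the sign of all. A list shifted by 0.5 on the log2 scale was recovered at a median of 0.48 as the only list of 27 past the threshold. Noise was drawn independently for each probe set, so neither result covers the correlation between genes on the real arrays. Other settings fixed beforehand were offsets of 1 and 50, leaving out the third of probe sets with the lowest mean, quantile normalization, median centring, an intensity trend, array weights, an ordinary test without moderation, leaving out probe sets that can match several transcripts, the replicate number as a block, and leaving out each array. For gene lists they also included an estimated correlation, fry and the mean of a gene's probe sets, and for the neighbourhood of ung-1 windows of 50 and 200 genes. Settings added after seeing the data were the restored values themselves, date cells set to missing, leaving out mutant replicate 3 and N2 replicate 2 together, the first component of the deviations within groups as a covariate, the base excision repair list without ung-1, and an unadjusted threshold.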

Results

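Whole-genome expression was measured in an ung-1 mutant of the nematode Caenorhabditis elegans, as the samples are labelled, and in the wild type strain N2, the standard laboratory strain of this worm. The gene ung-1 encodes uracil-DNA glycosylase, the enzyme that removes uracil from DNA at the start of base excision repair. Total RNA was hybridised to Affymetrix C. elegans genome arrays, with 3 arrays for the mutant and 3 for N2, named as biological replicates in the labels. The labels gave no stage, culture condition, DNA damaging treatment or allele, and the design text spoke of RNAi mutants where the sample labels spoke of a mutant. Values are probe set intensities in arbitrary units, given as mean ± SD with n = 3 in each group. Log2 fold changes are mutant minus N2 on the scale log2(intensity + 16), with limma standard errors.

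The 22548 probe sets tested named 17118 genes. The median intensity of an array lay between 152.82 and 160.985 in the mutant and between 158.315 and 167.85 in N2. Pairs of arrays correlated between 0.924 and 0.975 across probe sets, which are not independent replicates. The ratio of the 3' to the 5' control probe set of GAPDH, a sign of RNA integrity, was 6.62 ± 1.94 in the mutant and 10.2 ± 1.79 in N2 (two-sided exact permutation p = 0.2). It was 3.49 ± 0.84 and 4.53 ± 0.76 for actin (0.2) and 4.11 ± 0.26 and 4.92 ± 0.55 for ubiquitin (0.2). For catalase it was 28.1 ± 3.54 and 29.3 ± 1.44 (0.6). Each mean ratio was lower in the mutant, so a difference in RNA integrity between the genotypes stays open. On all 6 arrays the 3' probe set read higher than the 5' one for each of these controls. The ratio ran from 5.01 to 11.8 for GAPDH and from 25.9 to 32.2 for catalase. Both genotypes thus showed a bias to the 3' end, and its effect on the spread between replicates was not tested. The number of arrays limits the precision of every comparison, and 3 against 3 arrays cannot give an exact permutation p below 0.1. Of all cells in the value table, 1.003% held large whole numbers that match spreadsheet dates, and these were read back as the small intensities such dates stand for.

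The first comparison asked whether the ung-1 transcript was lower in the mutant. The ung-1 probe set gave 52.6 ± 4.30 in the mutant and 262 ± 30.6 in N2, a ratio of 4.98 between the N2 and mutant means. All 3 mutant arrays, from 47.67 to 55.33, lay below all 3 N2 arrays, from 235.93 to 295.57. The log2 fold change was -2.01 (SE 0.15, 95% confidence interval -2.37 to -1.66). The exact permutation p was 0.1, the smallest that 3 against 3 arrays allow. Benjamini-Hochberg adjustment of the limma p gave 4.07e-05 over the base excision repair list alone and 0.0765 over all probe sets, so that ung-1 did not pass the threshold over all probe sets. Where the probe set lies relative to any lost part of the gene is not given in the sources used here, and its identifier marks it as one that can match several transcripts. The adjusted p over all probe sets was 0.0118 with an intensity trend in the variance model, 0.0392 with array weights and 0.0276 with the values as deposited, the setting first planned, and it ranged from 0.0118 to 0.9996 over all alternatives. With the values as deposited, 5 probe sets with date numbers ranked ahead of ung-1 and lowered its adjusted p, while its unadjusted p was larger than with restored values.

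The second comparison asked which other genes differed between the mutant and N2. The transcripts of 6 core cell death genes fixed beforehand differed by less than the spread between replicates. The BH3-only genes egl-1 and ced-13, which start programmed cell death and are targets of the p53 homologue CEP-1, had log2 fold changes of 0.04 (95% confidence interval -0.39 to 0.48) and -0.19 (-0.69 to 0.31). The caspase gene ced-3 had -0.0063 (-0.76 to 0.74) and -0.14 (-0.60 to 0.33) on its 2 probe sets, and the Apaf-1 homologue ced-4 had -0.0033 (-0.50 to 0.50). The Bcl-2 homologue ced-9 had -0.05 (-0.49 to 0.38) and 0.11 (-0.26 to 0.48), and cep-1 had 0.06 (-0.27 to 0.39) and -0.20 (-0.77 to 0.38). The probe sets of ced-9 and of cep-1 thus differed in sign, with each change smaller in size than its own standard error. Adjusted p was 0.999 in limma for each of these 9 probe sets.

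No probe set passed a limma adjusted p of 0.05, with or without a minimum change of 2-fold. An unadjusted p under 0.05 was reached by 435 probe sets, against 1127.4 from chance alone, and an ordinary equal-variance test gave 0 past the adjusted threshold and 565 at the unadjusted one. Of the 435, 155 were higher and 280 lower in the mutant, while quantile normalization gave 190 higher and 240 lower and median centring 215 higher and 198 lower. The 3 mutant values lay apart from the 3 N2 values in 6.69% of probe sets, where chance gives 10%. On simulated arrays of this design, limma called 33 of 100 probe sets changed 2-fold and 93 of 100 changed 4-fold, with 8 false calls. The simulation changed 200 probe sets at once and drew independent noise for each. Its shares therefore need not hold for the real arrays, where ung-1, changed 4.04-fold, was not called. The 435 became 714, 233 and 831 without mutant replicates 1, 2 and 3, and 234, 232 and 894 without N2 replicates 1, 2 and 3, with 0 past the adjusted threshold in each case. The balance turned without mutant replicate 3, to 452 higher and 379 lower. It stood at 249 higher and 645 lower without N2 replicate 3, and the remaining settings also had more lower than higher.

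The genes lower and higher with the smallest unadjusted p, apart from ung-1, are given as values that did not pass (limma adjusted p 0.999 each). They were taken among probe sets that name 1 gene, have a mean above the 25th percentile and have all mutant arrays on one side of the N2 arrays. A probe set without a gene symbol had a smaller p than bath-30, and T05E12.6, below that percentile at 0.92 (SE 0.24), had a smaller p than acs-1. Among the lower ones, bath-30, a gene with BTB and MATH domains, gave 313 ± 56.5 in the mutant and 583 ± 68.5 in N2 (log2 fold change -0.88, SE 0.18). The BLOC-1 subunit gene blos-7 gave 102 ± 27.8 and 241 ± 51.3 (-1.14, SE 0.25), and Y56A3A.30 gave 58.4 ± 12.18 and 113 ± 16.3 (-0.80, SE 0.18). The cytoplasmic poly(A) polymerase gene gld-2 gave 425 ± 56.1 and 716 ± 84.5 (-0.73, SE 0.17). Among the higher ones, the cathepsin A-like gene ctsa-4.1 gave 418 ± 107.5 in the mutant and 183 ± 62.2 in N2 (1.14, SE 0.29). The UDP-glucuronosyltransferase genes ugt-16 and ugt-62 had log2 fold changes of 0.77 (SE 0.19) and 1.18 (SE 0.31), the acyl-CoA synthetase gene acs-1 of 0.56 (SE 0.15) and F54A3.6 of 1.09 (SE 0.29).

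**Figure D1:**
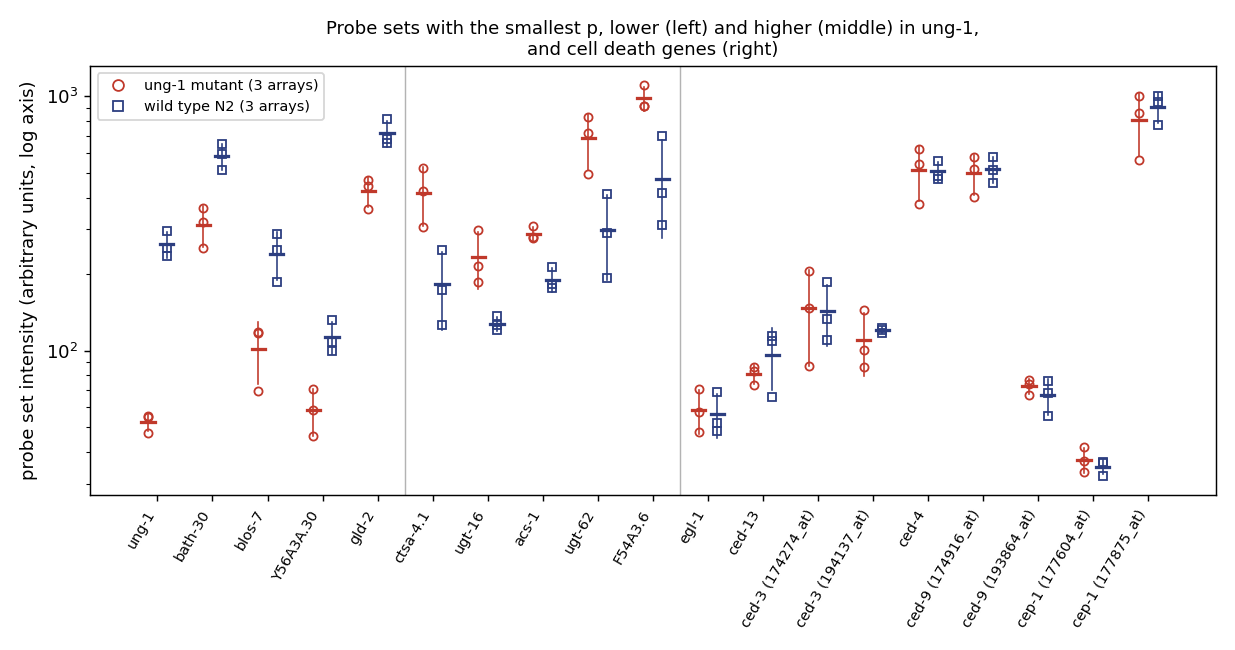
Probe set intensity in arbitrary units on a log axis for genes lower (left) and higher (middle) in the ung-1 mutant by smallest p, and for cell death genes (right). Open symbols are the 3 arrays of each group, thick bars the mean and vertical lines the SD; the genes left and middle were chosen with mutant and N2 arrays fully apart, as in ung-1 with 52.6 against 262, and the arrays of the cell death genes overlap.

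The third comparison asked whether groups of genes moved together, in 27 lists fixed before the data were examined. Against the other genes, camera with a preset correlation of 0.01 placed 6 lists higher and 2 lower in the mutant. The splits of the 6 arrays gave 7 to 15 lists by the same test. In each of the 8 lists the medians on single arrays overlapped between the genotypes. Rose and fell below give only the sign of the median fold change. No list passed with a correlation estimated from these arrays, and none passed fry's directional test. Fry's test of change in either direction passed for 1 list, base excision repair and uracil exclusion, which holds ung-1 (adjusted p = 0.000158, and adjusted p = 0.957 without ung-1). No member of any list passed limma's adjusted p over all probe sets, and ung-1 was the only member of any list to pass adjusted over the list alone. The median log2 fold change of all probe sets was -0.027.

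Cuticle collagens, the structural proteins of the worm's outer covering, were placed higher in the mutant, with overlapping arrays. Relative to each gene's mean, they stood at 0.15, -0.038 and 0.16 on mutant replicates 1, 2 and 3. On N2 replicates 1, 2 and 3 they stood at -0.28, -0.13 and 0.073. Their median log2 fold change was 0.26, with 122 of 147 genes positive (camera adjusted p = 8.15e-14, and adjusted p = 0.456 with an estimated correlation). The gene col-101 gave 736 ± 250 in the mutant and 367 ± 26.1 in N2 (0.92, SE 0.25), and col-98 had 0.77 (SE 0.30), neither past the threshold. The collagen median was 0.15 without mutant replicate 3, 0.13 without N2 replicate 1 and 0.15 without mutant replicate 3 and N2 replicate 2 together. Proteasome genes rose with a median of 0.20, and 29 of 36 were positive (adjusted p = 1.1e-09, and adjusted p = 0.624 with an estimated correlation). Relative to each gene's mean, this list stood at 0.12, 0.16 and 0.014 on mutant replicates 1, 2 and 3, and at -0.19, -0.17 and 0.087 on those of N2. Values not past the threshold were 0.47 (SE 0.15) for the core subunit gene pbs-7, 0.44 (SE 0.17) for pas-4 and 0.43 (SE 0.18) for the regulatory subunit gene rpn-10. The proteasome median was 0.11 without N2 replicate 1, 0.13 without probe sets that can match several transcripts and 0.31 with array weights.

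Fatty acid metabolism genes rose with a median of 0.13, and 68 of 96 were positive (camera adjusted p = 1.7e-06, and adjusted p = 0.696 with an estimated correlation). Besides acs-1, the peroxisomal thiolase gene daf-22 had 0.65 (SE 0.23) and the fatty acid elongase gene elo-5 had 0.51 (SE 0.21), values that did not pass. The call ended without mutant replicate 2, where the median was 0.038 (adjusted p = 0.118), and the median was 0.22 without mutant replicate 3 and 0.20 without mutant replicate 3 and N2 replicate 2 together. Oxidative stress and detoxification genes rose with a median of 0.050, and 115 of 194 were positive (adjusted p = 0.00302, and adjusted p = 0.831 with an estimated correlation). Besides ugt-16 and ugt-62, the cytochrome P450 gene cyp-13B1 had 0.66 and 0.70 on its 2 probe sets, values that did not pass. This call ended without N2 replicate 3, with a median of -0.0099 (adjusted p = 0.238), and the median was 0.13 without N2 replicate 2. It was 0.079 with quantile normalization, 0.093 with median centring, 0.10 with array weights and 0.13 without mutant replicate 3 and N2 replicate 2 together.

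Heat shock and unfolded protein response genes rose with a median of 0.14, and 23 of 35 were positive (camera adjusted p = 0.0072, and adjusted p = 0.456 with an estimated correlation). Members went both ways without passing, with 0.53 (SE 0.20) for the co-chaperone gene dnj-19, 0.71 (SE 0.35) for the Hsp70 gene hsp-1 and -1.13 (SE 0.47) for the small heat shock gene hsp-16.41. The call ended without mutant replicate 3 (median 0.082, adjusted p = 0.272) and without N2 replicate 2 (0.060, adjusted p = 0.131). Without probe sets that can match several transcripts, the median was -0.075 (adjusted p = 0.805), with array weights 0.040 (0.0622), and without mutant replicate 3 and N2 replicate 2 together 0.029 (0.8997).

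Major sperm proteins, the motility proteins of nematode sperm, rose with a median of 0.14, and 23 of 23 genes were positive (camera adjusted p = 0.0249, and adjusted p = 0.910 with an estimated correlation). The probe sets of this list share sequence and are not independent. The member msp-76 gave 1337 ± 553 in the mutant and 1042 ± 443 in N2, which did not pass. Mutant replicate 3 and N2 replicate 1 stood apart in this list, with medians of -0.89 and -0.82 relative to each gene's mean, where the other 4 arrays had 0.21 to 0.68. The median fold change was -0.050, -0.15 and 0.62 without mutant replicates 1, 2 and 3, and -0.20, 0.35 and 0.26 without N2 replicates 1, 2 and 3. The call ended without mutant replicate 1 (adjusted p = 0.530), mutant replicate 2 (0.889) or N2 replicate 1 (0.497), with quantile normalization (0.125), with median centring (0.0853), without the third of probe sets with the lowest mean (0.0531) and with the ordinary test (0.0701). The median was 0.84 with array weights and 0.85 without mutant replicate 3 and N2 replicate 2 together, a setting that keeps the low N2 replicate 1.

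Germline and oocyte genes fell, with a median of -0.17 and 30 of 36 negative (camera adjusted p = 0.0182, and adjusted p = 0.910 with an estimated correlation). The oocyte maturation gene oma-2 gave 2896 ± 100.9 in the mutant and 3854 ± 384 in N2 on one probe set, which did not pass, and the eggshell gene cpg-1 had -0.38 (SE 0.16). Mutant replicate 3 had a list median of -0.64 relative to each gene's mean, where the other 5 arrays had -0.024 to 0.33. Without that array the direction turned, with a median fold change of 0.14 (adjusted p = 0.0257). Without N2 replicate 3 it was -0.063 (adjusted p = 0.894), and without mutant replicate 1 it was -0.38. The call also ended with array weights (-0.028, adjusted p = 0.356), with the ordinary test (0.0701), without probe sets that can match several transcripts (0.0786), with the mean of a gene's probe sets (0.0923) and without mutant replicate 3 and N2 replicate 2 together (0.052, 0.786). Genes of male-enriched neurons fell with a median of -0.19, and 12 of 15 were negative (adjusted p = 0.0133, and adjusted p = 0.910 with an estimated correlation). The ion channel gene asic-2 gave 98.4 ± 19.9 in the mutant and 193 ± 73.05 in N2, which did not pass. The call ended without mutant replicate 2 (median -0.18, adjusted p = 0.0637), mutant replicate 3 (-0.14, 0.112) or N2 replicate 2 (-0.0039, 0.281), and the median was -0.28 without N2 replicate 3 and -0.12 with an offset of 50. It also ended with values as deposited (0.0573), with array weights (-0.11, 0.0810), without the third of probe sets with the lowest mean (0.0747) and without mutant replicate 3 and N2 replicate 2 together (-0.047, 0.799).

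The remaining 19 lists did not pass camera with all arrays, but 15 of them passed with 1 array left out. In DNA repair, the median log2 fold change was -0.044 for base excision repair and uracil exclusion (adjusted p = 0.132), -0.056 for nucleotide excision repair (0.840) and -0.019 for mismatch and double-strand break repair with the damage checkpoint (0.732). Here parp-2, a poly(ADP-ribose) polymerase gene, had -0.51 (SE 0.18) on one probe set and -0.15 (SE 0.17) on the other. On the probe set with the smallest p, rad-23 had 0.48 (SE 0.18), and polq-1, the gene of DNA polymerase theta, had -0.30 (SE 0.18). Cell death regulation and execution had a median of -0.0033 (0.734), with 15 genes positive and 16 negative, and engulfment and corpse degradation had -0.012 (0.938). Their members with the smallest p were ces-1, a Snail family regulator of cell death, at -0.35 (SE 0.14) and ced-7, an ABC transporter gene of engulfment, at -0.58 (SE 0.23). Each value is that of the probe set with the smallest p, and other probe sets of a gene can differ. DNA replication and cell cycle had -0.052 (0.738) and histones -0.024 (0.951), with mix-1 at 0.34 (SE 0.19) and hil-7 at 0.40 (SE 0.18). Base excision repair passed without mutant replicate 1 (median -0.16, adjusted p = 0.0477), mutant replicate 2 (-0.12, 0.0338) or N2 replicate 1 (-0.12, 0.0470), and with quantile normalization on all arrays (-0.023, 0.0492). It stood at 0.15 without mutant replicate 3 and with array weights. Without ung-1 itself, a setting added after the data were seen, this list had a median of -0.019 over 10 genes (adjusted p = 0.891). It also did not pass when any 1 of the 6 arrays was left out (camera adjusted p from 0.118 to 0.893). Mismatch and double-strand break repair passed upwards without mutant replicate 3 (0.16, 0.000512) or N2 replicate 3 (0.12, 0.0233). DNA replication passed upwards without the same arrays (0.17, 0.000187, and 0.021, 0.0425), also upwards without mutant replicate 3 and N2 replicate 2 together (0.14, 0.0317), and downwards without mutant replicate 1 (-0.18, 0.0368). Camera placed the nucleotide excision, mismatch and double-strand break, cell death, replication and histone lists above the other genes although their medians and means were negative.

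Among stage and tissue lists, yolk proteins had a median of -0.39 (camera adjusted p = 0.284), sperm 0.065 (0.0900), moulting 0.14 (0.0900) and embryonic lineage regulators -0.11 (0.0995). Body wall muscle had 0.025 (0.182), neurons -0.047 (0.546) and intestine 0.013 (0.0644), where the peptide transporter gene pept-1 gave 601 ± 132 in the mutant and 317 ± 88.7 in N2. Dauer and starvation genes had a median of 0.010 and a mean of -0.022 (0.546), and innate immunity genes had -0.11 (0.645). Ribosomal proteins had 0.011 (0.0640), mitochondrial respiration and ATP synthesis 0.0047 (0.0954), and RNA interference and small RNA genes 0.039 (0.0995). In the last list the nuclear Argonaute gene hrde-1 gave 57.1 ± 17.5 in the mutant and 118 ± 26.8 in N2, which did not pass. Without mutant replicate 1, the lists that passed were yolk (median -1.15, adjusted p = 0.0275), moulting (0.14, 0.0337), muscle (0.24, 0.00292), neurons (0.12, 0.0394), intestine (0.031, 0.0362), dauer (0.14, 0.0275), ribosome (0.021, 0.0337) and mitochondria (0.030, 0.0394). Moulting passed without mutant replicate 2 (0.42, 1.1e-05). Without mutant replicate 3, sperm (0.34, 9.5e-07), embryonic regulators (-0.11, 0.0223), neurons (-0.17, 0.0057), intestine (0.12, 0.00933), mitochondria (0.10, 0.000443) and small RNA genes (0.16, 0.0027) passed, while yolk stood at 0.15 and moulting at -0.19. Without N2 replicate 1, muscle (0.31, 6.7e-06), neurons (0.079, 0.0342), intestine (0.056, 0.00339) and ribosome (0.033, 0.00755) passed. Without N2 replicate 2, sperm (0.10, 0.04999), neurons (-0.19, 2.5e-05), intestine (0.11, 0.0158), ribosome (0.066, 0.00142) and mitochondria (0.15, 5.3e-05) passed. Without N2 replicate 3, sperm (0.19, 0.00543), moulting (0.41, 3.7e-05), innate immunity (-0.21, 0.0425) and small RNA genes (0.15, 0.000684) passed.

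Some of these lists also passed in other settings on all 6 arrays. Ribosomal proteins passed with an offset of 50 (adjusted p = 0.0359), median centring (median 0.054, 0.0133), an intensity trend (0.0379), the ordinary test (0.00760), without probe sets that can match several transcripts (0.039, 0.00342) and with the mean of a gene's probe sets (0.0315). With array weights, sperm (0.40, 1.1e-06), embryonic regulators (-0.16, 0.00205), neurons (-0.26, 0.000287) and mitochondria (0.12, 7.4e-05) passed. Embryonic regulators passed without the third of probe sets with the lowest mean (-0.24, 0.0371), and intestine (0.12, 0.0103) and mitochondria (0.038, 0.0369) with the mean of a gene's probe sets. Moulting passed with the replicate number as a block (0.0136) and with the first component of the deviations within groups as a covariate (0.0361). Without mutant replicate 3 and N2 replicate 2 together, sperm (0.40, 1.2e-06), embryonic regulators (-0.10, 0.0317), neurons (-0.33, 9.6e-09), intestine (0.24, 0.00321), ribosome (0.085, 0.0317) and mitochondria (0.23, 9.6e-08) passed. There moulting (-0.43, 2.6e-05) and muscle (-0.16, 0.00658) passed in the other direction, with N2 replicate 3, the N2 array highest in moulting, kept.

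**Figure D2:**
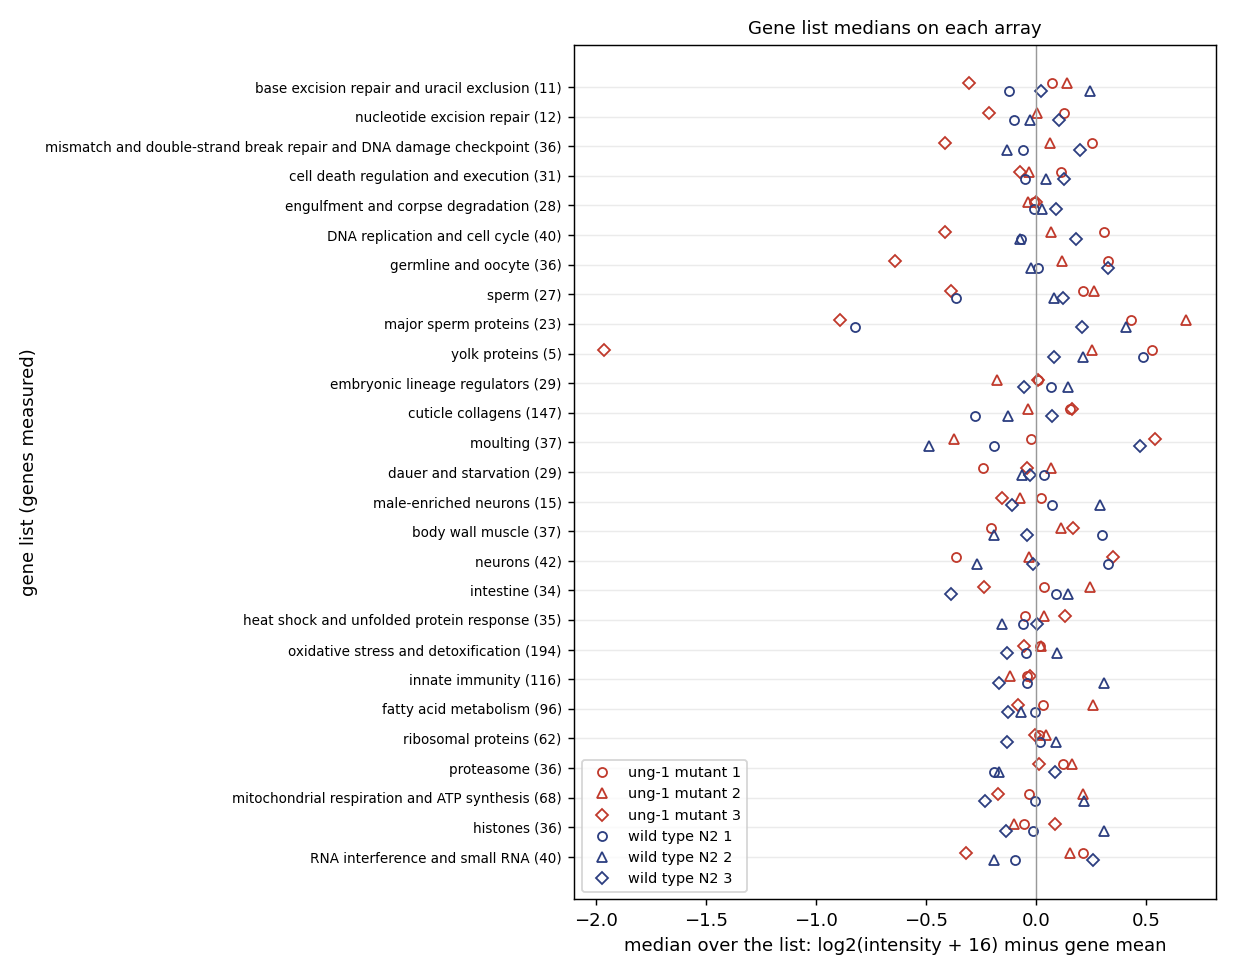
Median over each gene list of log2(intensity + 16) minus the gene's mean over the 6 arrays, on the horizontal axis, with the number of genes measured beside each list. Each symbol is 1 array (red for the mutant, blue for N2); yolk proteins on mutant replicate 3 lie at -1.97, and major sperm proteins on mutant replicate 3 and N2 replicate 1 lie at -0.89 and -0.82.

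The fourth comparison asked whether genes near ung-1 differed more often, since a strain carrying a mutant allele can differ from N2 at linked sites. Gene order was taken from assembly WBcel235, and ung-1 lies on chromosome III. Within 100 genes on either side of ung-1, none of 192 probe sets passed limma's adjusted p, and 4 (2.08%) had an unadjusted p under 0.05. This share was 1.796% in the rest of the chromosome (two-sided Fisher exact p = 0.776) and 1.90% in the rest of the genome (p = 0.787). One of the 4 was Y56A3A.30, the gene next to ung-1 in annotation order. The adjacent gene on the other side, Y56A3A.28, had a log2 fold change of 0.05 (SE 0.14).

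**Figure D3:**
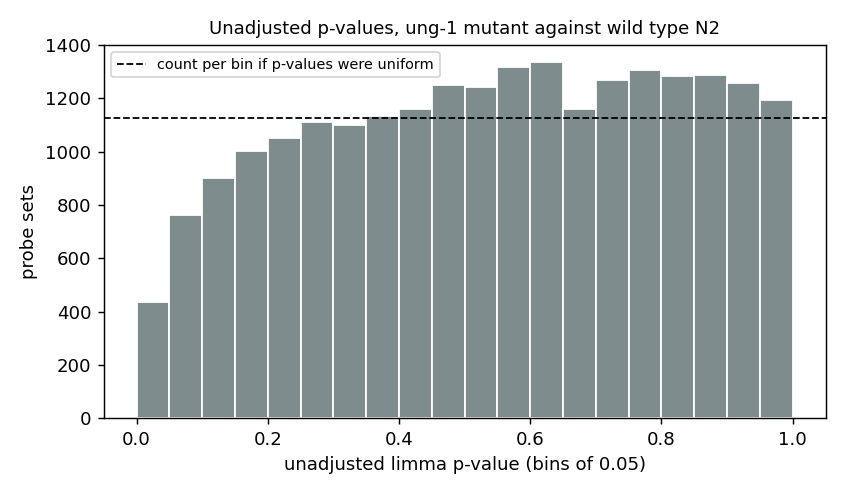
Number of probe sets in each bin of 0.05 of the unadjusted limma p for the mutant against N2. The dashed line is the count per bin if p-values were uniform, 1127.4, and the first bin holds 435 probe sets.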

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

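The restored values, the date cells set to missing, the fit without mutant replicate 3 and N2 replicate 2, the covariate and the unadjusted threshold were chosen after the data were seen. Both counts of probe sets past the adjusted threshold, with and without a 2-fold minimum, were 0 except for 1 with an intensity trend, 1 with array weights (ung-1 in each) and 6 with values as deposited, the setting first planned. The 6 were ung-1 and 5 probe sets with date numbers in every array of 1 group. The ung-1 change kept its sign and an unadjusted p under 0.05 in every alternative, from -2.29 (offset 1) to -1.60 (offset 50) and from -2.08 to -1.93 with 1 array left out; its adjusted p ranged from 0.0118 to 0.9996. Its probe set is among those that can match several transcripts, so no value exists without these. The 435 probe sets at the unadjusted threshold became 193 without the third of lowest mean (fewer tested), 1554 with array weights, 1197 without both doubted arrays and 664 with the covariate. The cause was not tested for the last 3. The arrays called doubted are mutant replicate 3 and N2 replicate 2, whose deviations ran against those of both other arrays of their genotype. Correlations were -0.723 and -0.586 for the mutant array and -0.610 and -0.743 for the N2 array. Deviations of 3 arrays sum to 0, so such values arise partly by construction and show no fault in an array. Leaving both doubted arrays out keeps N2 replicate 1, low in major sperm proteins (-0.82), and N2 replicate 3, high in moulting (0.47). That setting is therefore no check on the changes of these lists.

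Lists past the threshold numbered 8, against 0 with an estimated correlation, 0 with fry, 14 without both doubted arrays and 7 to 17 with 1 array left out (17 without mutant replicate 1, 14 without mutant replicate 3). Collagens and proteasome each kept the call in 21 of 23 alternatives, all except the estimated correlation and fry. Detoxification and fatty acid metabolism kept it in 20, heat shock in 16, germline in 14 and male-enriched neurons in 14 of 23, and major sperm proteins in 13 of 22, since without probe sets that can match several transcripts the last list could not be tested. With 1 array left out, medians changed sign in 21 of the 27 lists, 3 of them among the 8, and 15 of the 19 lists not past the threshold passed in at least 1 such setting (base excision repair in none once ung-1 was left out of it, a check chosen after the data were seen). Camera's direction turned, with a call before or after, for germline (-0.38 to 0.14), major sperm proteins (-0.20 to 0.62), DNA replication (-0.18 to 0.17) and neurons (-0.19 to 0.12, medians in brackets); for detoxification the median ranged from -0.0099 to 0.13 while camera's direction held. Without both doubted arrays it turned for germline (0.052), moulting (-0.43), body wall muscle (-0.16) and heat shock (median 0.029, placed below the other genes). The cause was not tested. None of the 797 alternative values of 41 named probe sets passed the adjusted threshold, and 27 changed sign. These are the probe sets named by the rule, without ung-1 and the moulting gene lin-42, and without genes chosen later. Signs changed only in cell death genes, msp-76 and vit-5. Many of the others were chosen for arrays fully apart or for the smallest p in a list, so their steady signs are no support. The neighbourhood of ung-1 held 0 calls in windows of 50, 100 and 200 genes, and 2, 4 and 9 probe sets at the unadjusted threshold.

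With the replicate number as a block, 0 probe sets passed, the limma adjusted p of ung-1 rose to 0.9996 (its fold change cannot move in this balanced design) and 9 lists passed, the 8 and moulting (adjusted p = 0.0136). Deviations of arrays with the same number correlated at -0.187, 0.090 and 0.104, and 3 of the 6 arrays were closest to their own number in the other group, so the numbers were not taken to pair the samples. Signal over background is unknown here and limits dim probe sets.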

Other observations

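The tests of the large whole numbers, of swapped labels, of stage and of a chance finding in Y56A3A.30, and the splits for both adjusted counts, were chosen after the result was seen. Transcripts of sexual maturity and moulting varied between arrays of the same genotype. The yolk protein gene vit-5 read 3609 on mutant replicate 3 and 17868 to 21698 on the other 5 arrays, and the yolk list median there was -1.97 relative to each gene's mean. The major sperm protein gene msp-76 read 723 on mutant replicate 3 and 583 on N2 replicate 1, against 1075 to 1796 on the other 4 arrays. The moulting list stood at 0.54 on mutant replicate 3 and 0.47 on N2 replicate 3, and at -0.37 and -0.49 on replicate 2 of each genotype. In this list noah-1, a gene of the apical extracellular matrix, read 1127 and 623 on the first pair and 283 and 207 on the second, on the dimmer of its 2 probe sets.

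Of 2981 genes with several probe sets, 6 had every probe set at an unadjusted limma p under 0.05 with 1 sign, none of them past the adjusted threshold (adjusted p 0.999 each). The venom allergen-like gene vap-1 was lower in the mutant on 3 probe sets, with log2 fold changes from -1.13 to -1.05. Higher in the mutant were T05E12.6 (0.92 and 1.13), cyp-13B1 (0.66 and 0.70), acaa-2, an acetyl-CoA acyltransferase gene (0.55 and 0.63), test-1 (0.43 and 0.60) and tufm-1, the gene of a mitochondrial elongation factor (0.47 and 0.70).

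The first pattern was the set of large whole numbers in a table otherwise written with decimals. True saturated intensities are argued against by the share of them, 99.8%, that are days of 1 calendar year or firsts of a month. Small values read as dates by a spreadsheet, the reading used for the main values, were tested on the intact values and remain a candidate explanation: all 37 intact values from 13 to 31 with decimals 01 to 12 form dates that do not exist. The deposited numbers matter for the biology, since as deposited bli-4, fbxa-169, math-6 and E02C12.10 appeared lower and C05D12.4 higher in the mutant at log2 fold changes between -10.3 and 9.93, against -0.15 to 0.48 once restored. Probe sets with a 2-fold difference between means numbered 516 as deposited, 452 of them with a date cell, and 65 once restored.

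The second pattern was the shortage of small p-values, 435 against 1127.4 from chance, with genotype holding 12.8% of the variance where 20% is expected with no effect. The count exceeded that from chance with array weights (1554) and without mutant replicate 3 and N2 replicate 2 together (1197). Of the 10 splits of the arrays, 2 gave fewer than the real one, in a range from 302 to 2113. The shortage thus depends on the setting and is not particular to the real split. Differences in scaling are argued against by quantile normalization, which left 98.8% of the median SD within groups, and labels swapped between genotypes by a gap in ung-1 of 3.03 times the largest range within a genotype. Differences in stage or germline content between arrays of 1 genotype remain a candidate explanation: 6 of 6 stage and germline lists varied within groups above the 95th percentile of 10000 matched random lists. So did 7 of the 21 other lists, among them neurons, intestine and innate immunity, so the variation was not confined to stage markers. Embryonic lineage regulators, also a stage marker, were counted among the 21. They varied less than matched random lists did at the median (SD 0.199 against 0.237). The random lists were drawn gene by gene and lack the correlation between genes of the real lists. For the 6 stage and germline lists this was estimated from 0.098 in cuticle collagens to 0.966 in major sperm proteins. The 95th percentile is too low for such lists, so the test cannot decide whether their spread is unusual. Culture or RNA differences were not tested as a cause of this shortage, and the labels give no stage.

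The third pattern was Y56A3A.30, next to ung-1 and lower in the same 3 arrays. A wider difference between the strains around ung-1, as an excess of neighbours with an unadjusted p under 0.05, is argued against only for large excesses: without Y56A3A.30 the odds ratio was 0.824 (95% confidence interval 0.168 to 2.46) within 100 genes, from 3 probe sets, and 0.567 (0.0142 to 3.26) within 50. A smaller excess stays open. A chance finding among the genes searched stays open too: its p adjusted over the 192 probe sets of the planned window was 0.628. A comparison with the nearest genes of other genes and an adjustment over the 2 nearest genes on either side were both set aside as void after their results were seen, since the gene had been noticed for its rank. A shared effect of the allele or shared probes was not tested.

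The 6 arrays allow 10 splits into 3 against 3, too few for a share under 0.05. Probe sets past the adjusted threshold, with or without the 2-fold minimum, numbered 0 in the real split and at most 0 in the others; against a real count of 0 all 10 splits give as many by construction, which says nothing about chance. The count at the unadjusted threshold was 435 in the real split and at most 2113 in the others (8 splits gave as many), and the count of lists 8 against at most 15 (9 splits). The split with 2113, the largest count, set mutant replicates 1 and 2 with N2 replicate 3 against the rest. What this split reflects was not tested. For ung-1, this permutation of the arrays set a limma p of 3.39e-06 in the real split against a smallest p of 1.4e-05 for any probe set in another, and 1 split, the real one, gave a p as small.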
